A study of Homo sapiens with 12 samples.

How the data were processed

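Expression was measured in HaCaT cells, a line of human keratinocytes, after 4 h with 0.1% DMSO or with obacunone at 10, 50 or 100 µM. Each of the 4 groups had 3 arrays, numbered by the labels as sets 1, 2 and 3, for 12 arrays in all. Total RNA was extracted with Trizol and amplified to biotinylated cRNA with an Illumina TotalPrep kit, per the labels. The labels do not say whether the 3 replicates of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The share of DMSO in the treated cultures is not given in the sources used here.

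The deposited table holds the average bead intensity of 18189 probes on each array, not normalized between arrays, with values from 12.3 to 28645.3. It also holds a detection p-value for each probe and array, per the file headers. The scanner software, its version and any filter on probes are not given in the sources used here. A separate deposited table holds log2 values. Sorted within each array, these equalled quantile-normalized log2 signals without background correction, with a largest gap of 1.19e-06. Probe by probe, the largest gap to such values made here with limma was 0.00133. The deposited log2 values were used as an alternative.

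Background was corrected with the normexp model of neqc in limma 3.58.1 (R 4.3.3), with the background mean and SD inferred from the detection p-values and an offset of 16, followed by quantile normalization and log2. The inferred background lay above the signals of undetected probes. Its mean was 91.6 to 144 and its SD 101 to 241, whereas probes with a detection p above 0.5 had median signals of 52.5 to 71.1 with a median absolute deviation of 2.97 to 6.11. Detection p was not a function of signal alone: 101 to 133 probes per array were brighter than the median detected probe and still not detected, and the Spearman correlation of signal and detection p across probes was -0.961 to -0.952. The values as planned were kept, and normexp fitted on the signals alone (mean 40.0 to 59.5, SD 1.40 to 3.39) was added as an alternative after the data were seen. The inferred background can shift the fold changes of dim genes, so each fold is on this corrected scale.

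Probes with a detection p under 0.05 on all 3 arrays of at least 1 group were kept, 9773 in number. Of the 18189 probes, 16425 had 1 gene symbol in the platform annotation, 0 had several and 1764 had no listed gene. Entrez IDs of 16407 probes were found in a human reference gene table (assembly GRCh38.p14), which changed 0 symbols. The kept probe with the highest mean log2 value stood for its gene, which gave 8977 genes. Of these, 18 had more than 1 kept probe. The 778 kept probes with no listed gene stayed out of the tests of genes. Probe coordinates were not used here. The number of arrays limits the precision of every value.

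Each dose was compared with vehicle, and neighbouring doses with each other, in 1 limma model of all 12 arrays (lmFit, contrasts.fit and eBayes, 8 residual degrees of freedom), and a moderated F test compared the 4 groups. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene counted as changed at an adjusted p under 0.05. In all, 34 gene lists from textbook knowledge were tested with camera in limma at a preset inter-gene correlation of 0.01 and again with an estimated correlation. The 29 lists with 3 or more tested members gave 87 tests against vehicle, adjusted together. Of these tests, 17 passed at the preset correlation and 0 with the estimated one, where the smallest adjusted p was 0.0532. Median or mean and test differed in sign in 20 of the 87, of which 0 passed. List tests between doses, 58 in number, were added after the data were seen.

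The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined, apart from those said to be added. For each dose against vehicle, the rule took up to 10 rises and 10 falls with the largest change among genes that passed and whose 3 treated values all lay beyond the 3 vehicle values. Where no gene passed, it took the 3 genes with the smallest p. For each list it took up to 4 members that passed with the largest change, or the member with the smallest p. Genes named because they passed with the replicate block were chosen after their values were seen, as were the genes named between doses.

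The set numbers were checked for pairing before the calls of the fits were compared. The deviations of arrays from their group means correlated at 0.738 to 0.879 in all 18 pairs of arrays with the same set number, and at -0.621 to -0.0469 in the 36 pairs of different sets and groups. The deviations of a group sum to 0, so the negative values between sets follow from the high ones within sets and add no support. By the values within sets, the numbers paired the arrays. A fit with the set as a block (replicate block, 6 residual degrees of freedom) is therefore given beside a result where it changed a call or moved a count by over 1.5 times. What a set shared, such as a day or a culture, is not stated.

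The fits were tested on simulated data with 8977 genes for 100 µM against vehicle. Without the block, 47 of 100 genes changed by 0.5 on the log2 scale and 89 of 100 changed by 1 were recovered, with 0 false calls. With the block, 95 and 100 were recovered, with 8 false calls (3.94% of calls). A list of 15 genes raised by 0.3 had a camera p of 1.07e-27, and 0 of 99 unchanged lists fell under 0.05. The simulated arrays were built from set differences and the spread of the fit with the block. That fit's better recovery was thus built in and does not weigh whether the block suits the real arrays. The spread was drawn independently for each gene and the lists were random genes, so lists of correlated genes were not simulated. The false calls of the real lists, whose calls differed between the preset and the estimated correlation, were therefore not checked. Other alternatives were no background correction, an offset of 50, median scaling, other filters on dim probes, the mean of a gene's probes, all kept probes, only the groups compared, a trended robust variance model, array weights and each array left out in turn. The turns that left out 1 array were run without the block, so they also left the sets unequal between groups. Slide as a block was not run, because neither the tables nor the labels give a slide. Figures were drawn with matplotlib 3.10.9.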

Results

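HaCaT is a spontaneously immortalized line of human keratinocytes, and obacunone is a limonoid found in citrus fruit. RNA of HaCaT cells was measured on 12 Illumina bead arrays after 4 h with vehicle (0.1% DMSO) or with obacunone at 10, 50 or 100 µM, with 3 arrays per group. The arrays detected 9862 to 10451 of 18189 probes (54.2% to 57.5%). The mean of the arrays' median signals was 112 ± 8.21 (SD, n = 3) in vehicle, 104 ± 21.3 at 10 µM, 96.2 ± 9.34 at 50 µM and 117 ± 27.4 at 100 µM. Arrays of the same replicate set resembled each other more than arrays of the same dose. Log2 values correlated across genes at 0.991 to 0.998 within a set and at 0.979 to 0.990 within a dose group, and 68.9% of the variance lay between sets against 18.8% between dose groups. Principal component 1 held 44.8% of the variance. Component 3 held 13.2% and ordered the arrays of every set from vehicle through 10 and 50 to 100 µM.

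**Figure D1:**
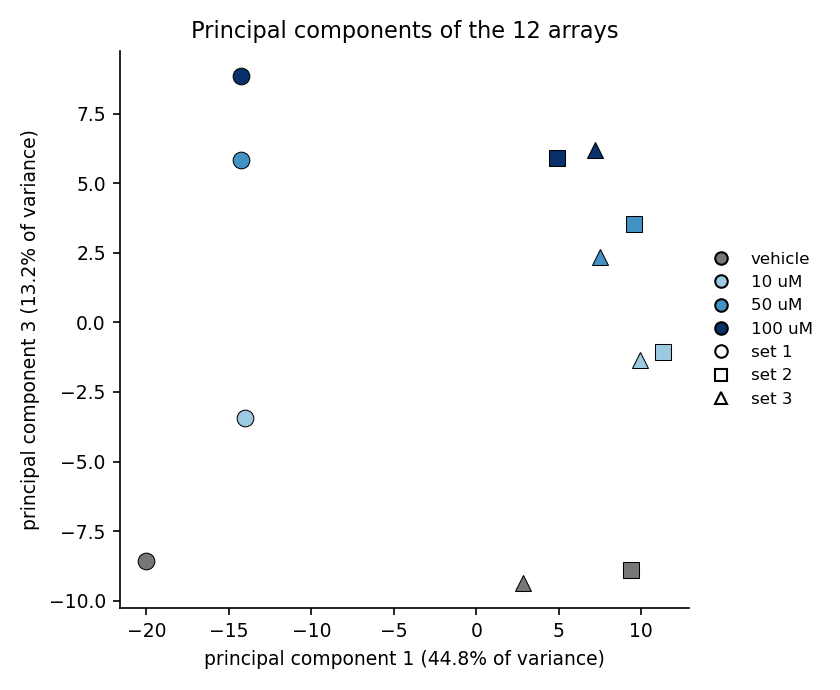
Scores of the 12 arrays on principal components 1 (x axis, 44.8% of variance) and 3 (y axis, 13.2%) of the log2 values, with colours for the dose groups and marker shapes for the replicate sets. On component 3 the vehicle arrays lie between -9.34 and -8.57 and the 100 µM arrays between 5.91 and 8.85.

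The first comparison asked which transcripts differed after the lowest dose. At 10 µM, genes of cholesterol synthesis and uptake were higher as a group. The median of 17 tested members was 0.13 above vehicle on the log2 scale, 13 members were above 0, and the medians within sets 1, 2 and 3 were 0.09, 0.14 and 0.05. Immediate early genes, which respond within minutes to many stimuli, had a median of 0.10, with 14 of 17 above 0. The cholesterol list passed camera (adjusted p = 0.000487, but adjusted p = 0.448 with an estimated correlation), as did the immediate early list (adjusted p = 0.00811, and adjusted p = 0.406 with an estimated correlation). No member of either list passed alone, and 0 did so when adjusted over the list alone. The cholesterol list did not pass without vehicle array 2 (median 0.10, adjusted p = 0.178) or 10 µM array 1 (0.16, adjusted p = 0.0873), nor the immediate early list without 10 µM array 1 (0.08, adjusted p = 0.167). The median of 19 G1/S cell cycle genes was 0.04, with an adjusted p of 0.0534 and of 0.0327 with the replicate block (0.281 with the block and an estimated correlation). That list passed without 50 µM array 3 (adjusted p = 0.0375) or 100 µM array 1 (0.0485). Other lists that passed at 10 µM when 1 array was left out were ER chaperones (median 0.12, adjusted p = 0.00524) and fatty acid synthesis (0.08, 0.0223) without 10 µM array 2, NRF2 targets (0.04, 0.0370) without 10 µM array 3 and ATF4 targets (0.10, 0.04996) without vehicle array 1. Calls with 1 array left out used the preset correlation, and an estimated one was not run for them.

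Calls of single genes at 10 µM depended on the fit. The 3 genes with the smallest p were RAPGEF1, an exchange factor for the GTPase Rap1, at 0.38 (SE 0.05), HELZ2, a helicase and nuclear receptor coactivator, at 0.43 (SE 0.06) and EVI5L at 0.35 (SE 0.06). Their adjusted p was 0.0925, 0.0925 and 0.407. Of 8977 genes, 0 passed the limma test without the block and 285 had an unadjusted p under 0.05. These 285 are a smaller share than the 0.05 that unchanged genes would give. The fit without the block counts the differences between sets as spread, so its few calls do not show that genes were unchanged. With the replicate block, 1528 genes had an unadjusted p under 0.05 and 41 passed, 30 higher and 11 lower. Among the 41 were all of RAPGEF1, HELZ2 and EVI5L (adjusted p = 0.0151, 0.0101 and 0.0293). None of these calls was left in the same limma fit without set 1, 2 or 3, which gave 0 genes each time (1715, 1223 and 783 at an unadjusted p under 0.05). Without background correction the block gave 74 higher and 100 lower, and with normexp on the signals alone 31 higher and 36 lower. In the block fit on the values as planned FASN, the fatty acid synthase, was 0.39 higher and was the only member of any list to pass. TOB1, an antiproliferative gene, was 0.54 higher, whereas the splicing genes PNN and SRSF7 were at -0.67 and -0.44.

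The second comparison set 50 µM against vehicle. Several genes of sterol and lipid synthesis rose, with calls that each depended on single arrays in the fit without the block. INSIG1, which retains the sterol sensor SCAP in the endoplasmic reticulum (ER), rose 4.31-fold, from a log2 signal of 7.88 ± 0.29 (SD, n = 3) to 9.99 ± 0.69. MVD, the mevalonate diphosphate decarboxylase, rose 2.71-fold, and HMGCS1, the synthase of HMG-CoA, 2.61-fold. Of the 17 cholesterol genes 9 rose, 0 fell and the others did not pass, and 10 rose when adjusted over the list alone. Their median was 0.51, with 0.79, 0.44 and 0.51 within the sets (camera, adjusted p = 1.75e-19, and adjusted p = 0.0763 with an estimated correlation). DHCR7, SQLE and SC5D, enzymes of later sterol synthesis, rose by 1.18, 0.80 and 0.79. Of 9 fatty acid synthesis genes 3 rose and 0 fell, and 4 rose when adjusted over the list alone. These were LPIN1, a phosphatidate phosphatase, at 1.11, FASN at 0.72 and the desaturase SCD at 0.34 (list median 0.24, adjusted p = 0.000111, and adjusted p = 0.0763 with an estimated correlation). With the replicate block 13 cholesterol genes and 4 fatty acid genes rose, the latter with ACLY at 0.61.

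Stress response lists had smaller medians at 50 µM than the cholesterol and fatty acid lists, a difference that was not tested. Of 24 targets of NRF2, the regulator of antioxidant genes, 1 rose, PGD of the pentose phosphate pathway, by 0.47 (SE 0.08), and 4 rose when adjusted over the list alone. The list median was 0.15 (adjusted p = 1.16e-05, and adjusted p = 0.0992 with an estimated correlation). With the block 6 NRF2 targets rose, among them the thioredoxin reductase TXNRD1 at 1.38 and the sulfiredoxin SRXN1 at 0.74. ER chaperones had a median of 0.16 over 19 genes (adjusted p = 0.00136, and adjusted p = 0.448 with an estimated correlation), and 0 members passed, also when adjusted over the list alone (1 with the block). The 18 targets of ATF4 in the integrated stress response had a median of 0.12, and all 18 were above 0 (adjusted p = 0.0406, and adjusted p = 0.660 with an estimated correlation). TRIB3 of that list was at 0.46 (adjusted p = 0.0809, 0.0240 with the block). Immediate early genes had a median of 0.11 (adjusted p = 0.000487, and adjusted p = 0.245 with an estimated correlation), with 0 members passing. The ATF4 list did not pass without vehicle array 2 (median 0.04), vehicle array 3 (0.05), 10 µM array 1 (0.12) or 50 µM array 1 (-0.02), nor the ER list without 50 µM array 1 (0.06). Lists that passed with the block and not without it were, on all arrays, heat shock (median 0.12, adjusted p = 0.0786 against 0.0272) and matrix proteases and matrix (-0.10, 0.163 against 0.0272), and with the block and an estimated correlation their adjusted p was 0.507 and 0.430. Without the block, heat shock also passed without vehicle array 1 (median 0.18, adjusted p = 0.00405), 50 µM array 2 (0.21, 0.00394) or 50 µM array 3 (0.15, 0.0482), and ERK pathway genes passed without vehicle array 2 (0.16, 0.0235).

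Among other named genes at 50 µM, the immune ligands TNFSF9 and MICB rose by 0.81 and 0.80, and the clock repressor BHLHE40 by 0.79. VEGFA, of the hypoxia and glycolysis list, rose by 0.28, or 0.69 with normexp on the signals alone. Of that list's 17 members 1 rose, and 3 rose and 1 fell when adjusted over the list alone, but the list did not pass (median -0.05, adjusted p = 0.575). All 6 genes that fell were TIMM9, a chaperone of mitochondrial import, at -0.75 (SE 0.11), the myosin light chain MYL12A at -0.50, the protease inhibitor SERPINB1 at -0.45, LYRM1 at -0.41, STEAP1 at -0.40 and SUSD1 at -0.40. In all, 32 of 8977 genes passed limma, 26 higher and 6 lower, with adjusted p from 0.0224 upward. Of these 14 changed over 1.5-fold and 5 over 2-fold. With the replicate block 506 genes passed, 263 higher and 243 lower, and all 32 were among them. That count was 138, 17 and 0 (1568 at an unadjusted p under 0.05) without sets 1, 2 and 3, and more genes were lower than higher without background correction (387 higher, 485 lower) and with normexp on the signals alone (303 higher, 383 lower). Leaving out a vehicle or 50 µM array in the fit without the block also left the sets unequal between groups. In that fit the count of 32 depended on each array. It was 14, 0 and 0 without vehicle arrays 1, 2 and 3, 13, 18 and 13 without the 10 µM arrays, 2, 8 and 7 without the 50 µM arrays, and 11, 13 and 14 without the 100 µM arrays. It was 0 with median scaling and 10 with normexp on the signals alone. Of the 32 genes, 0 passed in all 12 turns of leaving out 1 array. INSIG1, LPIN1, SQLE, BHLHE40, TNFSF9 and PGD failed in 12 of 12 turns, HMGCS1 in 9, MVD in 6 and DHCR7 and FASN in 4. The INSIG1 change stayed between 1.71 and 2.33 on the log2 scale in these turns, and was 2.11, as with all arrays, where a 10 or 100 µM array was left out and only the estimate of the spread changed.

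In the comparison of 100 µM with vehicle, sterol and lipid synthesis genes were again among the largest rises. INSIG1 rose by 3.00 on the log2 scale, to a log2 signal of 10.88 ± 0.20 (SD, n = 3) from 7.88 ± 0.29, with rises of 2.94, 2.93 and 3.13 within the sets (limma, adjusted p = 0.00236). MVD rose 4.19-fold, HMGCS1 3.36-fold, DHCR7 2.91-fold and SQLE 2.54-fold. Of 17 cholesterol genes 10 rose and 0 fell, also when adjusted over the list alone, and all 17 were above 0. Their median was 0.80, with 1.11, 0.82 and 0.71 within the sets (camera, adjusted p = 1.48e-27, and adjusted p = 0.0532 with an estimated correlation). Of 9 fatty acid genes 4 rose, LPIN1 (1.69), the citrate lyase ACLY (1.12), FASN (0.83) and SCD (0.44), and 4 rose when adjusted over the list alone. That list's median was 0.39 (adjusted p = 4.76e-07, and adjusted p = 0.0532 with an estimated correlation). With the replicate block 14 cholesterol genes rose, including MSMO1 (1.72), IDI1 (0.72), FDPS (0.70) and EBP (0.50), which did not pass without it.

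**Figure D2:**
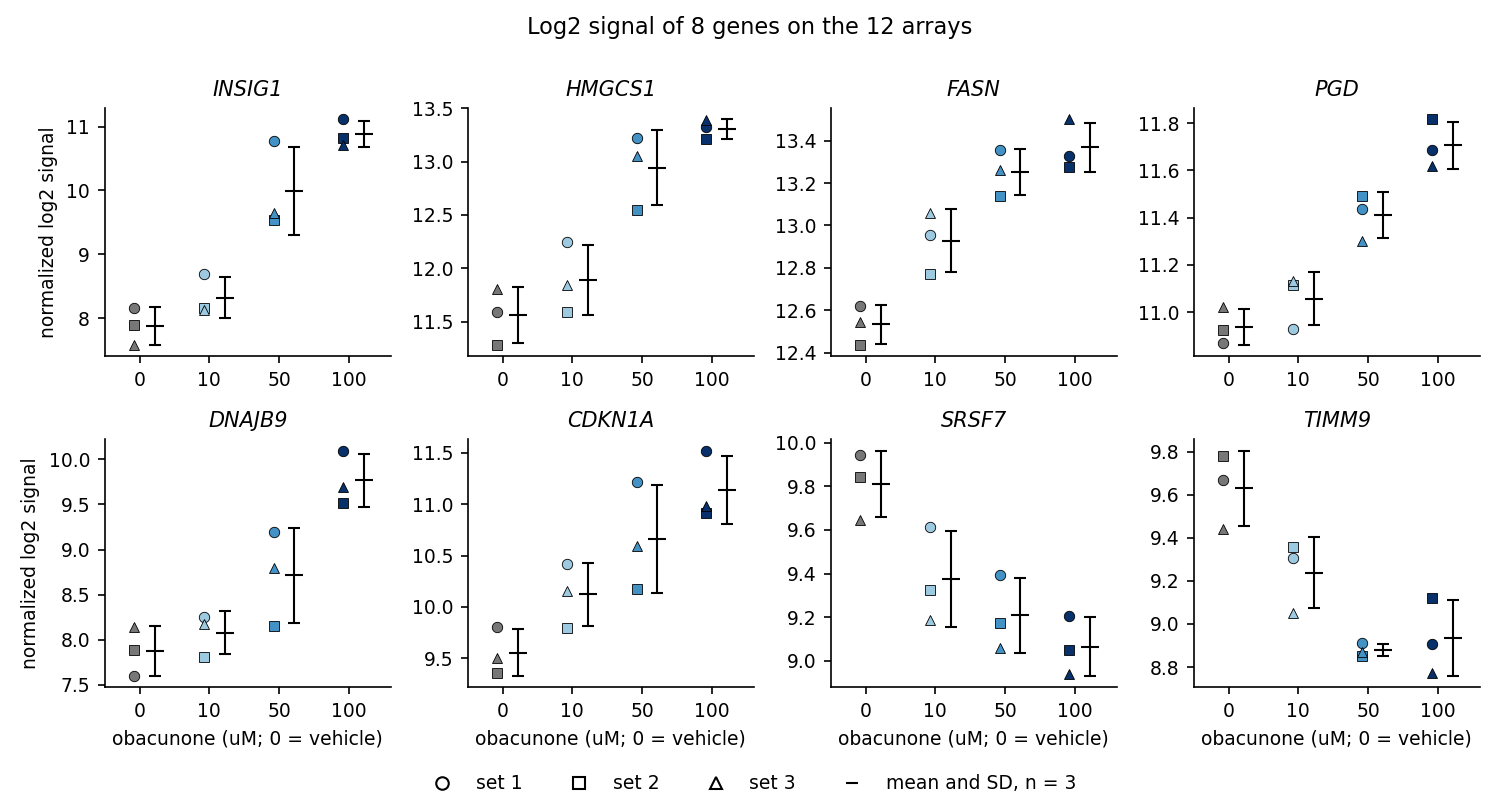
Normalized log2 signal (y axis) of INSIG1, HMGCS1, FASN, PGD, DNAJB9, CDKN1A, SRSF7 and TIMM9 on the 12 arrays by dose of obacunone in µM (x axis), with marker shapes for the replicate sets and bars for the mean ± SD of 3 arrays. INSIG1 goes from a mean of 7.88 in vehicle to 10.88 at 100 µM, and SRSF7 from 9.81 to 9.06.

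ER chaperone genes were higher as a group at 100 µM, although few passed alone. DNAJB9, an ER co-chaperone, rose 3.71-fold (log2 1.89, SE 0.26) and HSPA5, which encodes BiP, 1.75-fold. Of 19 genes of the list 2 rose, 12 when adjusted over the list alone and 10 with the block, among these HERPUD1 of ER-associated degradation at 1.39. All 19 were above 0 with a median of 0.32 (adjusted p = 3.75e-12, and adjusted p = 0.0992 with an estimated correlation). Of 18 ATF4 targets 1 rose, the pseudokinase TRIB3 by 0.81, also when adjusted over the list alone, and 6 with the block. The median was 0.32, with all 18 above 0 (adjusted p = 3.56e-06, and adjusted p = 0.448 with an estimated correlation). Of 24 NRF2 targets 1 rose, PGD by 0.77, 6 when adjusted over the list alone and 11 with the block, among these TXNRD1 (1.70), SRXN1 (0.93), the glutathione synthesis gene GCLM (0.88) and the quinone reductase NQO1 (0.46). That list's median was 0.21 (adjusted p = 1.16e-07, and adjusted p = 0.0763 with an estimated correlation). The heat shock list had a median of 0.20 over 16 genes (adjusted p = 0.00439, and adjusted p = 0.497 with an estimated correlation), with 0 members passing, also when adjusted over the list alone, and 8 rising with the block. Among these were DNAJB1 (0.95) and HSPA1B (0.86), whose transcripts are nearly identical to those of HSPA1A, so its value is uncertain. The heat shock list did not pass without vehicle array 2 (median 0.15, adjusted p = 0.0602) or 100 µM array 1 (0.13, adjusted p = 0.302).

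The immediate early, circadian and ribosome biogenesis lists also passed camera at 100 µM, though not with an estimated correlation. Immediate early genes had a median of 0.12 over 17 genes (adjusted p = 0.000144, and adjusted p = 0.196 with an estimated correlation). Of these 0 passed, 1 rose when adjusted over the list alone and 3 rose with the block, including JUND at 0.77. Circadian clock genes had a median of 0.10 over 8 genes (adjusted p = 0.0302, and adjusted p = 0.196 with an estimated correlation), and 1 of them rose, BHLHE40 by 1.35, also when adjusted over the list alone. That list did not pass without vehicle array 1 (0.06, adjusted p = 0.0769), vehicle array 2 (0.10, adjusted p = 0.0519) or 100 µM array 3 (0.05, adjusted p = 0.0930). Ribosome biogenesis genes were lower as a group, with a median of -0.16 over 15 genes and 1 above 0 (adjusted p = 0.00439, and adjusted p = 0.0987 with an estimated correlation). No member passed, also when adjusted over the list alone, and 2 fell with the block, NOP58 (-0.45) and NOP16 (-0.25).

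**Figure D3:**
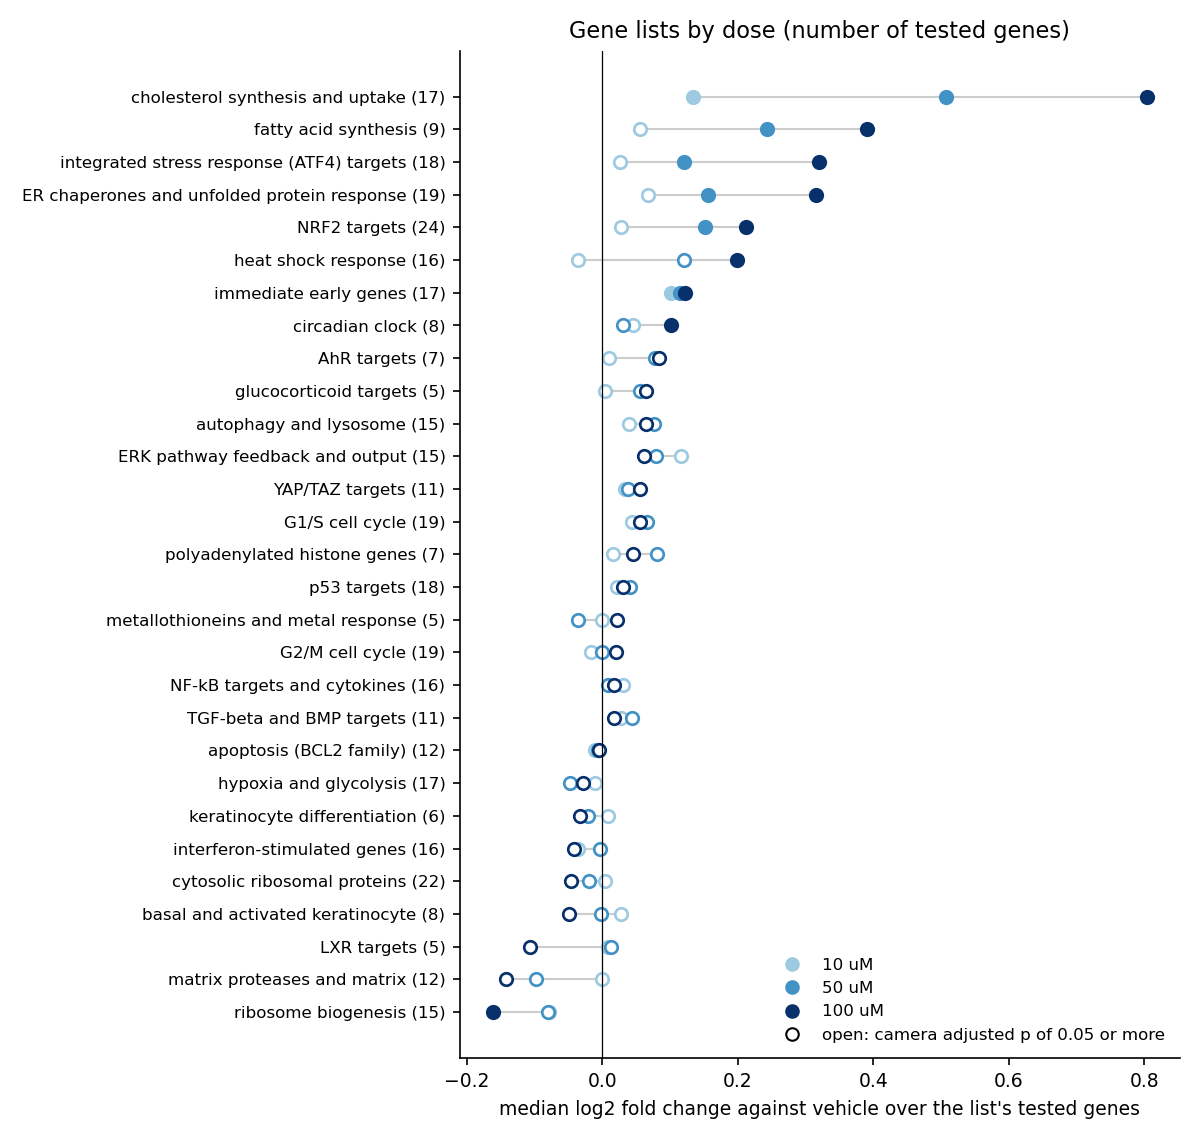
Median log2 fold change against vehicle (x axis) of the tested members of 29 gene lists (y axis) at 10, 50 and 100 µM (colours), with filled points where the list passed camera at the preset correlation. The cholesterol list goes from 0.13 at 10 µM to 0.80 at 100 µM, and none of the 17 filled points passes with an estimated correlation.

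The other lists did not pass at 100 µM. The medians of cell growth and fate lists were 0.06 for G1/S genes, 0.02 for G2/M genes, 0.03 for p53 targets and -0.00 for the BCL2 family. CDKN1A, the cell cycle inhibitor p21, was the 1 of 18 p53 targets that rose, 3.00-fold (log2 1.59, SE 0.27), also when adjusted over the list alone. Its probe was detected on 3 of 3 arrays at 100 µM and on 2 of 3 in each of the other groups. Keratinocyte differentiation genes had a median of -0.03, basal and activated keratinocyte genes -0.05, matrix genes -0.14, TGF-beta and BMP targets 0.02, YAP/TAZ targets 0.06 and ERK pathway genes 0.06. The medians were 0.02 for NF-kB targets, -0.04 for interferon-stimulated genes, 0.08 for AhR targets, -0.11 for LXR targets, 0.06 for glucocorticoid targets, 0.02 for the metal response, 0.06 for autophagy and lysosome, -0.05 for cytosolic ribosomal proteins, 0.04 for histone genes and -0.03 for hypoxia and glycolysis. In the last, ALDOC and VEGFA rose by 0.31 and 0.23, 2 of 17 genes (3 when adjusted over the list alone), and VEGFA was 0.60 higher with normexp on the signals alone. The corrected scale can shrink changes of dim genes, so small medians do not show that these lists were unchanged. For example, ABCA1 (LXR list), HRK (BCL2 family) and CYP1A1 (AhR list) were at -0.13, -0.09 and 0.08. Over the other settings they ranged from -0.75 to -0.10, from -0.57 to -0.07 and from 0.05 to 0.29. With the block, matrix genes (adjusted p = 0.0303) and autophagy genes (0.0272) passed, but not with the block and an estimated correlation (0.430 and 0.281). LXR targets passed without 10 µM array 3 (median -0.11, adjusted p = 0.0470) or 100 µM array 1 (-0.14, 0.0191). Members that passed with the block and not in the fit without it were MMP1 (-0.78), MMP10 (-0.57), IL1B (-0.77), CXCL1 (-0.51), the LXR target MYLIP (-0.71) and the autophagy genes SQSTM1 (0.48) and GABARAPL1 (0.56). Few markers of other cells were tested, and lists with under 3 tested members had no test. Their medians at 100 µM were 0.08 for EGFR ligands (2 genes), 0.01 for melanocyte (2), 0.03 for fibroblast (1), 0.02 for immune (1) and 0.02 for endothelial markers (2).

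Other large rises at 100 µM were TNFSF9 (1.49) and BHLHE40 (1.35). The falls were smaller. The splicing factor SRSF7 fell by 0.75 on the log2 scale (SE 0.13, adjusted p = 0.0363), the homeobox gene DLX1 by 0.72, TIMM9 by 0.70, SERPINB1 by 0.52, the GPI anchor gene PIGC by 0.51, NTPCR by 0.47, the Wnt receptor FZD4 by 0.44, LYRM1 by 0.42 and the ribosome assembly gene WDR74 by 0.39. MECOM was lower by 1 kept probe (-0.40) and not by its other kept probe (0.02), so it is uncertain. At 10 and 50 µM these genes were at -0.44 and -0.60 for SRSF7, -0.27 and -0.57 for DLX1, -0.27 and -0.45 for PIGC, -0.45 and -0.49 for NTPCR, -0.11 and -0.28 for FZD4, -0.23 and -0.27 for WDR74 and -0.05 and -0.19 for MECOM. Among the rises DNAJB9 was at 0.20 and 0.84 and CDKN1A at 0.57 and 1.10, and CDKN1A also passed at 50 µM with the block (adjusted p = 0.00310).

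In all, 75 of 8977 genes passed limma at 100 µM, 61 higher and 14 lower. Of these 37 changed over 1.5-fold and 14 over 2-fold, all 14 higher. With the replicate block 761 genes passed, 412 higher and 349 lower, and all 75 were among them. That count was 291, 262 and 56 without sets 1, 2 and 3, with 59, 61 and 27 of the 75 among them. Without background correction the block gave 500 higher and 537 lower. In the fit without the block, the count of 75 was 45, 33 and 42 without vehicle arrays 1, 2 and 3 and 33, 38 and 39 without 100 µM arrays 1, 2 and 3. It was 19 with median scaling, 49 with normexp on the signals alone and 23 with only the 2 groups compared. Of the 75 genes, 27 passed whichever single array was left out, among them INSIG1, MVD, HMGCS1, DHCR7, LPIN1, SQLE, BHLHE40 and TNFSF9. SERPINB1, LYRM1 and FZD4 were the named falls that did so. DNAJB9 failed in 3 of 12 turns (highest adjusted p = 0.0587), CDKN1A in 8 (0.138) and SRSF7 in 9 (0.141).

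Further comparisons set neighbouring doses against each other. From 10 to 50 µM, the median of the 17 cholesterol genes was 0.54 higher, and all sets were above 0 (0.77, 0.31 and 0.41). The list passed camera (adjusted p = 3.30e-42), also with an estimated correlation (adjusted p = 0.0181), as did fatty acid synthesis (median 0.20, adjusted p = 0.0218 with an estimated correlation) and NRF2 targets (0.09, 0.0382). With the block and an estimated correlation these were 0.128, 0.153 and 0.153. From 50 to 100 µM the cholesterol median was 0.32 higher (adjusted p = 3.33e-22, and adjusted p = 0.0382 with an estimated correlation) and the fatty acid median 0.10 (3.91e-05, and adjusted p = 0.0429 with an estimated correlation). The ER list's median was 0.17 higher, with all 19 genes above 0 (adjusted p = 3.25e-14, and adjusted p = 0.0606 with an estimated correlation). In the fit with the block, the cholesterol and fatty acid lists had an adjusted p of 0.153 and 0.171 with an estimated correlation.

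No single gene passed limma between neighbouring doses on these values. From 10 to 50 µM 0 of 8977 genes passed (92 at an unadjusted p under 0.05, smallest adjusted p 0.382), and 0 with the block (510, 0.0834). From 50 to 100 µM 0 passed (125 at an unadjusted p under 0.05), and 0 with the block (650, 0.332). With the block and no background correction, 23 genes were higher at 50 than at 10 µM, 12 of them of the cholesterol list, led by INSIG1 at 1.37 (SE 0.12, adjusted p = 1.14e-05) and HMGCS1 at 1.02 (SE 0.10, adjusted p = 4.12e-05). With the block and normexp on the signals alone there were 16, 11 of them of that list. From 50 to 100 µM the block without background correction gave 3 genes, DNAJB9 (0.86), INSIG1 (0.80) and BHLHE40 (0.50).

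The last comparison tested any difference among the 4 groups, and the doses were then set beside each other. The 61 genes that rose at 100 µM had medians of 0.18, 0.42 and 0.66 at 10, 50 and 100 µM, and the 14 that fell had medians of -0.24, -0.40 and -0.43, where choosing genes by their change at 100 µM favours a larger value there. Among them 56 of 61 were higher at 50 than at 10 µM and 13 of 14 lower, an order that this choice does not favour, although genes are not independent replicates. The F test passed 33 genes (307 with the block, and 54, 0 and 0 with the block and without sets 1, 2 and 3). It passed 14 to 31 when 1 array was left out, the lowest without 100 µM array 1, and 7 with median scaling. At 50 and 100 µM, 25 genes were higher and 5 lower at both doses, and 0 went opposite ways. Independent lists would share 0.177 and 0.00936, and simulated unchanged groups against the same vehicle arrays shared 0 and 0. Unchanged groups give almost no calls to share, so that simulated overlap does not weigh the part of the vehicle arrays. With the block 184 and 166 were shared. Log2 fold changes across genes, which are not independent replicates, correlated at 0.835 between 10 and 50 µM, 0.668 between 10 and 100 µM and 0.871 between 50 and 100 µM, where unchanged simulated groups gave 0.498, 0.50 and 0.50. The covariances were 0.0148, 0.0134 and 0.0226 against simulated 0.00217, 0.00218 and 0.00218. The 3 vehicle arrays are too few to split, so part of the shared values may come from them. The overlap of 30 genes was 0 to 16 when 1 array was left out.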

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

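In this part, the tests of the cholesterol list, of the handling of the vehicle arrays, of the higher genes at 10 µM, of the sets in the regroupings and of the splits of 6 arrays were chosen after the results were seen. A signal appeared outside the tests of genes: of 778 kept probes with no listed gene, 7 changed at 100 µM, all 7 higher (limma, adjusted over all kept probes). With the replicate block 60 of them changed, 38 higher and 22 lower. No explanation was tested for these probes.

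Cholesterol synthesis and uptake genes were higher at 100 µM in every set. The tables argue against array brightness, since the 100 µM array was brighter than vehicle in set 1 (by 34.2 units of median signal) and dimmer in sets 2 and 3 (-8.84 and -8.13), while the lowest of the 3 list medians was 0.714. They also argue against the background correction or normalization, since the lowest list median over 4 other ways to make the values was 0.707. The list's median rose from 10 through 50 to 100 µM in 3 of 3 sets, which is consistent with a graded response to obacunone. That stays a hypothesis, because it was found on the same arrays, separate cultures are not stated, and the DMSO share of treated cultures is not known here.

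Genes that differed at 100 µM tended to lie on the same side of vehicle already at 10 µM, when the 100 clearest genes in each direction were chosen in the other sets and measured in the set left out. For the higher genes the medians at 10 µM were 0.212, 0.152 and 0.178, past 0.1 in the set with a brighter 10 µM array (0.212) and in those with a dimmer one, which argues against chance values of the vehicle arrays and against brightness. For the lower genes they were -0.04, -0.16 and -0.06, with 56, 82 and 68 genes below 0, and the median nearest to 0, -0.0369, which was also that of the set with the brighter array, leaves chance values and brightness open. The vehicle array was the least correlated of its set in 3 of 3 sets, which separate handling of vehicle and a response to treatment would both give, so these cannot be told apart. A response at 10 µM may therefore be real, but these arrays do not tell it from separate handling of vehicle.

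Splits of the arrays were counted for each comparison. For 50 and 100 µM against vehicle the real split gave 32 and 75 genes, the highest other split 0 and 0, and 1 of 10 splits gave as many in each, where 10 splits are too few for a share under 0.05. At 10 µM and between neighbouring doses all 10 of 10 splits gave 0 genes. Other splits that parted all pairs of arrays gave at most 0 genes with the block, where the real ones gave 41, 506 and 761. For the F test 2 of 100 regroupings of the 12 arrays, the real one included, gave at least 33 genes. Most of these regroupings break the balance of sets that the real groups keep, so they cannot exclude chance. The other of these 2 gave 140 genes, which points to a structure of the arrays. It was among the 16 of 99 regroupings, the real one aside, that had a group with arrays of 1 set only. Of these 16, 3 gave any gene, and the highest of the 83 without such a group was 18, so the sets are a candidate source that was not tested further. Among regroupings within sets 1 of 100 gave as many genes, the real one (highest other 17). With the block it was likewise 1 of 100 (307 genes, highest other 90), though several other regroupings also gave some genes. This is the smallest share that 100 regroupings can give, so it argues against chance there without excluding it.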

How the results depend on the processing

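The alternatives that combine the block with another choice, that fit normexp on the signals alone or that leave out a set were chosen after the data were seen. In the counts below, shared genes are those called in the same direction at 50 and 100 µM (main value 30). The replicate block, whose pairing the arrays bear out, gave 41, 506 and 761 genes at 10, 50 and 100 µM, 307 by the F test and 350 shared, and apart from the calls given in the report it changed no list call and lost none. No background correction and the deposited log2 values each gave 11 genes at 50 µM, 49 at 100 µM and 10 shared, and normexp on the signals alone gave 10, 49 and 10, with 21 by the F test. Median scaling gave 0, 19 and 0, with 7 by the F test. Without a filter on dim probes there were 16 genes at 50 µM and 15 shared, and with detection on all 12 arrays 21 at 50 µM. Only the 2 groups compared gave 0, 23 and 0, where fewer arrays leave fewer degrees of freedom, and a trended robust variance model gave 8, 47 and 8. A linear trend on dose passed 78 genes, 68 higher and 10 lower, of which 28 were among the 33 of the F test. The block without background correction gave 174 (74 higher), 872 (387 higher) and 1037 (500 higher) genes at the 3 doses, 23 from 10 to 50 µM, 3 from 50 to 100 µM, 749 by the F test and 557 shared. The block with normexp on the signals alone gave 67 (31 higher), 686 (303 higher) and 861 (437 higher) genes, 16 from 10 to 50 µM, 532 by the F test and 432 shared. The block with median scaling gave 3, 69 and 139 genes, 53 by the F test and 49 shared; the 139 were 93 higher and 46 lower. With the block and set 1 left out there were 0 genes at 10 µM, 138 at 50 µM, 291 at 100 µM, 54 by the F test and 117 shared, without set 2 0, 17, 262, 0 and 17, and without set 3 0, 0, 56, 0 and 0. Leaving out 1 array in turn, without the block, gave 0 genes at 10 µM, 0 to 18 at 50 µM, 33 to 68 at 100 µM, 0 between neighbouring doses, 14 to 31 by the F test, 0 to 16 shared and 14 to 19 lists. With an estimated correlation 0 of 17 lists passed, and fry's directional test, which asks whether a list's genes move one way without comparing them with other genes, lost 7 of the 17. Of 231 values of named genes 0 changed sign where either value passed, while 53 values under other settings changed sign with neither passing. Genes that passed without the block had all treated values beyond the vehicle values, so leaving out arrays could not change their sign. Over 7134 comparisons of these values with other settings, 657 calls were lost, 324 of them with 1 array left out. Only values that passed in the main fit could lose a call. The 7134 also hold the values that did not pass, so they are not the base for a share of lost calls. At 100 µM DHCR7, FASN, HMGCS1, INSIG1, LPIN1, MVD and PGD passed in all 31 other settings run for single genes. INSIG1 at 100 µM was 3.00 on the log2 scale as reported and 2.58 without background correction. Apart from the smaller fits, the cause of these shifts was not tested. The signals of dim genes lie near background, which limits their fold changes. Slide as a block was not run, since no slide is given.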

Other observations

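In this part, the mitochondrial ribosomal family and the comparison of dose ratios were chosen after the data were seen; the tests of that family were set before their results. The 41 genes that passed at 10 µM with the block all passed in the same direction at 50 µM, 30 higher and 11 lower. Of these, 29 and 10 passed at 100 µM. At 10 and 50 µM independent lists would share 0.879 and 0.298 and simulated unchanged groups 0 and 0.01. Independent lists ignore that both doses were compared with the same vehicle arrays, and unchanged groups give almost no calls to share. These values therefore cannot tell a shared response from chance values of the vehicle arrays. None of the 41 calls was left without set 1, 2 or 3, where the same fit gave 0 genes at 10 µM (limma, 1715, 1223 and 783 at an unadjusted p under 0.05). Those fits also have fewer residual degrees of freedom, so lost calls alone do not show that the changes rest on every set. The 41 genes included BRD2, a reader of acetylated chromatin (0.36, 0.47 and 0.56 at 10, 50 and 100 µM), the transcription factor ELF4 (0.34, 0.45 and 0.49), TOB1 (0.54, 0.80 and 0.86), COQ10B of coenzyme Q function (0.38, 0.63 and 0.80) and the RNA-binding gene IGF2BP3 (-0.48, -0.46 and -0.43).

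Genes of the mitochondrial ribosome, which translates the RNAs of the mitochondrial genome, were mostly lower at 100 µM. Of 74 tested genes 64 were below 0, with medians of -0.07, -0.09 and -0.11 at 10, 50 and 100 µM, and 13 fell with the block, among them MRPL40 (-0.45), MRPS33 (-0.42), MRPL51 (-0.40) and MRPL16 (-0.39), where 0 passed without it. The family was picked from these arrays, so no p-value is given for it. A dependence of the change on signal level alone is argued against, since 10000 random lists matched on mean log2 value centred on -0.00825, with a lowest median of -0.0858. Because the family was picked from these arrays, that comparison does not weigh chance. A graded response may account for it, but the family was lower at 100 than at 10 µM in 2 of 3 sets, so this stays open. Within sets 1, 2 and 3 the medians were already -0.09, -0.06 and -0.06 at 10 µM, against -0.11, -0.05 and -0.13 at 100 µM. Separate handling of the vehicle arrays could also give such values and was not tested for this family.

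A hypothesis was that ER genes need a higher dose than cholesterol genes. The change at 50 µM was 66.2% of that at 100 µM in the median of 14 cholesterol genes and 45.3% in the median of 10 ER genes that rose with the block at 100 µM (two-sided permutation test across genes, 100000 resamples, p = 0.00109, where genes are not independent replicates). As the ratio of the list medians over all 17 and 19 tested members, it was 63.0% against 49.3% in the fit of all sets. By that ratio cholesterol genes were ahead in sets 1 (71.3% against 60.9%) and 3 (70.9% against 66.6%) and not in set 2 (54.0% against 55.9%). As the ratio of the medians of the 14 and 10 genes the order was the opposite (63.5% against 68.2%), so the hypothesis stays open.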
